A study of Mus musculus with 22 samples.

How the data were processed

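Total RNA of mouse adipose tissue had been hybridised to Affymetrix Mu11K oligonucleotide arrays, per the labels. The A array held 6584 probes and the B array 6595, each including 55 control probes. The authors deposited 1 whole-number intensity per probe and array; between 0.668% and 5.41% of an array's values lay below 0. The software, scaling target and background step behind these deposited intensities are not given in the sources used here. Log files of hybridisation and scanning, per the file headers, held no expression value and were read only for chip type, chip lot and scan day.

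Groups came from the sample titles: 6 lean and 5 obese RNAs. The A and B arrays of an RNA were joined by title. Over 71 genes with a mean log2 intensity above 11 on both arrays, the A array correlated best with the B array of its own RNA for 6 of 11 RNAs (median r over genes 0.489, against -0.118 with other RNAs); genes are not independent replicates. No 2 arrays held identical values. Spearman correlation between arrays, across probes, was 0.875 to 0.968 on A and 0.808 to 0.974 on B. The scan names formed 2 sets, which also differed in scan day. On A, set 1 was scanned on 1 day and set 2 on the other 2; on B, set 2 was scanned on 1 day and set 1 on the other 2.

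Each array was scaled so that its 2% trimmed mean equalled the mean of these over the 11 arrays of its type (1209.51 on A, 1298.27 on B). Values under a floor of 10% of that target (120.951 and 129.827) were set to the floor and log2 was taken. Differences of genes near the floor are therefore understated. The share of values at the floor was 7.17% to 11.4% on A and 8.26% to 17.8% on B. Probes entered when above the floor in at least 5 of the 11 RNAs, control probes excluded, which left 6077 on A and 6031 on B. Gene names came from the platform annotation, with 7591 probes having 1 symbol, 224 several and 5364 none. Only probes with 1 symbol were named. No genome coordinates are given, because the sources used here name no build.

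Signal over background sets the limit of detection. Control probes for yeast genes, used as a background level, had median scaled intensities of 130 to 247 on A and 147 to 353 on B. Where the lower of the groups compared had a mean no higher than the top of that range, it is said to lie at background, and the size of the difference is uncertain. The ratio of 3' to 5' Gapdh control probes, a measure of RNA integrity, was 0.858 to 1.10 on A and 0.819 to 1.06 on B. On the B arrays the 3' Gapdh probe read 13693 and 13764 in the obese B6 and BTBR RNAs and at least 17585 in the others. The first principal component held 30.8% of the variance and the second 17.4%.

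Tests used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment over all 12108 probes and a threshold of 0.05. Obese was compared with lean over 11 RNAs without covariates. A slope per step over the stated glucose order was fitted to the 5 obese RNAs. Strain and sex were fitted together in the 6 lean RNAs, and a strain by obesity interaction in the 6 RNAs of B6 and BTBR. For the share of obesity-changed probes whose glucose slope had the same sign, an exact permutation over the 120 orders was used. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Each gene entered with 1 probe, the one with the highest mean, and lists needed 5 measured genes. A list score is the mean, over its genes, of the log2 deviation from each gene's mean over the 11 RNAs.

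The groups, tests, 23 gene lists and rule for named genes were fixed before the data were examined. The lists were adipocyte identity, fatty acid and triglyceride synthesis, cholesterol synthesis, oxidative phosphorylation, TCA cycle and fatty acid oxidation, thermogenic, insulin and glucose handling, macrophage, acute phase and inflammation, lymphocyte, class II antigen presentation and extracellular matrix. The others were cytoskeleton, skeletal muscle, mammary and epithelial, male reproductive tract, endothelial and pericyte, blood cell, sex-linked, proliferation, chaperones and endoplasmic reticulum stress, redox and glutathione, and cytosolic ribosome. Named were the 8 largest rises and 8 largest falls among passing probes, or, where fewer than 5 passed, the 8 probes with the smallest p. Up to 4 list members with the smallest p and 16 preset genes were also named. Xist and Ddx3y were preset for the sex comparison, but the Xist probe was too dim to enter and Ddx3y had no probe with a single symbol. Where a gene had several probes, the one with the smallest p is named and the others are given beside it where they differed for a gene among the largest changes or the preset genes.

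The procedure was tested on simulated data with 200 of 12108 probes changed. For obese against lean, 1.49% of 67 probes changed 1.41-fold, 62.7% of 67 changed 2-fold and 95.5% of 66 changed 4-fold were recovered, with 7 false calls. For the glucose slope, 46.3% of 67 probes changing 1.41-fold per step and 100% of 66 changing 2-fold per step were recovered. For 2-fold changes, 19.4% of 67 were recovered in BTBR against B6, 11.9% in F1 against B6 and 19.4% in female against male, with 8, 12 and 16 false calls over all sizes (5.93%, 8.76% and 10.3% of calls). For 4-fold changes, 71.6% of 67 were recovered in BTBR against B6, 77.6% in F1 against B6 and 89.6% in female against male. For the interaction, 0 of 66 probes changed 8-fold were recovered. These simulations held no batch difference.

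Alternatives planned beforehand were the values as deposited, quantile normalization, floors of 5% and 20%, no filter and a stricter filter on dim probes, no variance trend, the scan set as a block, scan set 1 alone, strain (B6, BTBR or cross) as a covariate and each lean sex alone. Also planned were an exact permutation and a Wilcoxon test per probe, a 2-fold minimum, other orders and subsets for glucose, other strain models and leaving out each RNA in turn. Scan set 2 alone, the A array alone, a joint fit of lean and obese B6 and BTBR, and several list tests were added after the data were seen. For comparisons within lean RNAs, a scan set block equals leaving out the BTBR lean female. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.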

Results

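Adipose tissue RNA was profiled from lean mice and from obese mice homozygous for the ob mutation, which removes functional leptin, the satiety hormone made by adipocytes. There were 11 RNAs, each read on an A array and a B array, so 22 arrays in all. The 6 lean RNAs were 1 female and 1 male each of C57BL/6J (B6), of BTBR, a strain used in studies of insulin resistance, and of their F1 cross. The 5 obese RNAs were 1 each from B6, from BTBR and from F2 mice with low, medium and high plasma glucose; their sex was not labelled. The labels did not say whether an RNA came from 1 animal or from a pool, so the p-values below measure the spread between these RNAs. Median deposited intensity was 589 to 784 on the A arrays and 545 to 764 on the B arrays. The number of RNAs, not a read depth, limits the precision. The scan names fell into 2 sets. Set 2 held the obese B6, the obese BTBR and the BTBR lean female RNAs, and set 1 held the other 8. In all, 12108 probes entered the tests, of which 7103 carried 1 gene symbol.

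The first comparison asked which genes differ between obese and lean adipose tissue. Several of the largest rises were in genes known from macrophages and other leukocytes. Mmp12, the macrophage elastase, was at the floor in all 6 lean RNAs and averaged 3681 ± 1047 (SD, n = 5) scaled units in the obese ones, at least 29.4-fold higher (adjusted p = 6.05e-09). C3ar1, a receptor for complement fragment C3a, rose by 3.36 ± 0.28 (log2 ± SE), from 222 ± 87.6 (SD, n = 6) to 2168 ± 501 units. Ccl2, a chemokine that attracts monocytes, rose by 3.05 ± 0.19, with 5 of the 6 lean RNAs at the floor. Itgb2, a leukocyte integrin subunit, rose by 3.10 ± 0.38, and Slc11a1, a metal transporter of phagosomes, by 2.82 ± 0.38. Adgre1, which encodes the macrophage antigen F4/80, rose by 2.65 ± 0.26. The lean means of C3ar1, Ccl2, Slc11a1 and Adgre1 lay within the range of the background probes, so the sizes of these differences are uncertain. Capg, an actin-capping protein, rose by 3.35 ± 0.19 on 1 probe, and its other 2 probes gave 0.20 and 1.69. Mpeg1, a pore-forming protein of macrophages, rose 7.99-fold on 1 probe (SE 0.38 in log2), while its other probe gave a log2 difference of -0.09. All 8 of these genes had obese values above every lean value. Of the 8 largest falls described next, 7 had obese values below every lean value. Both sets were picked as the largest passing differences, which favours such separation.

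The largest falls included several enzymes and transporters. Cyp2e1, a cytochrome P450, fell by 3.27 ± 0.23, from 22217 ± 4272 (SD, n = 6) to 2412 ± 889 (SD, n = 5) units (adjusted p = 8.65e-07). Gsta3, a glutathione transferase, changed by -2.12 ± 0.30, and Thrsp, a regulator of lipid synthesis, by -1.77 ± 0.18. Pxmp2, a peroxisomal membrane protein, changed by -1.60 ± 0.16 and Slc5a6, a vitamin transporter, by -1.65 ± 0.27. Net1 changed by -1.74 ± 0.35 and Zfp467, a zinc finger protein, by -1.58 ± 0.28. Krt19, an epithelial keratin, changed by -1.83 ± 0.40. Against the 3 lean males alone, where fewer RNAs entered, Krt19, Net1 and Zfp467 gave -1.65, -1.45 and -1.14 and no longer passed (adjusted p = 0.105, 0.0642 and 0.0759). Against the 3 lean females alone Krt19 gave -2.01 (adjusted p = 0.0528).

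Over all probes, 342 rose and 209 fell by limma, 551 of 12108 (named genes: 182 up, 136 down). Of these, 218 rises and 82 falls were at least 2-fold. An unadjusted p under 0.05 was reached by 2131 probes, against 605.4 by chance. The obese and lean values did not overlap in 540 of all 12108 probes (4.46%), against 52.4 by chance (0.433%). With the scan set as a block, 413 rose and 238 fell. Within scan set 1, 354 rose and 172 fell. Within scan set 2, which has 1 lean RNA, limma passed 0 probes (1448 at an unadjusted p under 0.05). Without the BTBR lean female RNA, the only lean RNA of scan set 2, 952 probes passed, in a fit where obesity and scan set are partly confounded. An exact permutation test per probe and a Wilcoxon test passed 0 probes after adjustment (1998 and 1602 at an unadjusted p under 0.05), with smallest adjusted p = 0.0769 and 0.0971. C3ar1, with fully separated groups, had p = 0.00216 by permutation and 0.00433 by Wilcoxon, and these same adjusted p. Full separation therefore did not pass by either test. The number of RNAs sets the smallest p a probe can reach. Too few probes reached it to pass after adjustment. The 0 counts therefore reflect both the number of RNAs and the data, and these tests support no single limma call.

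**Figure D1:**
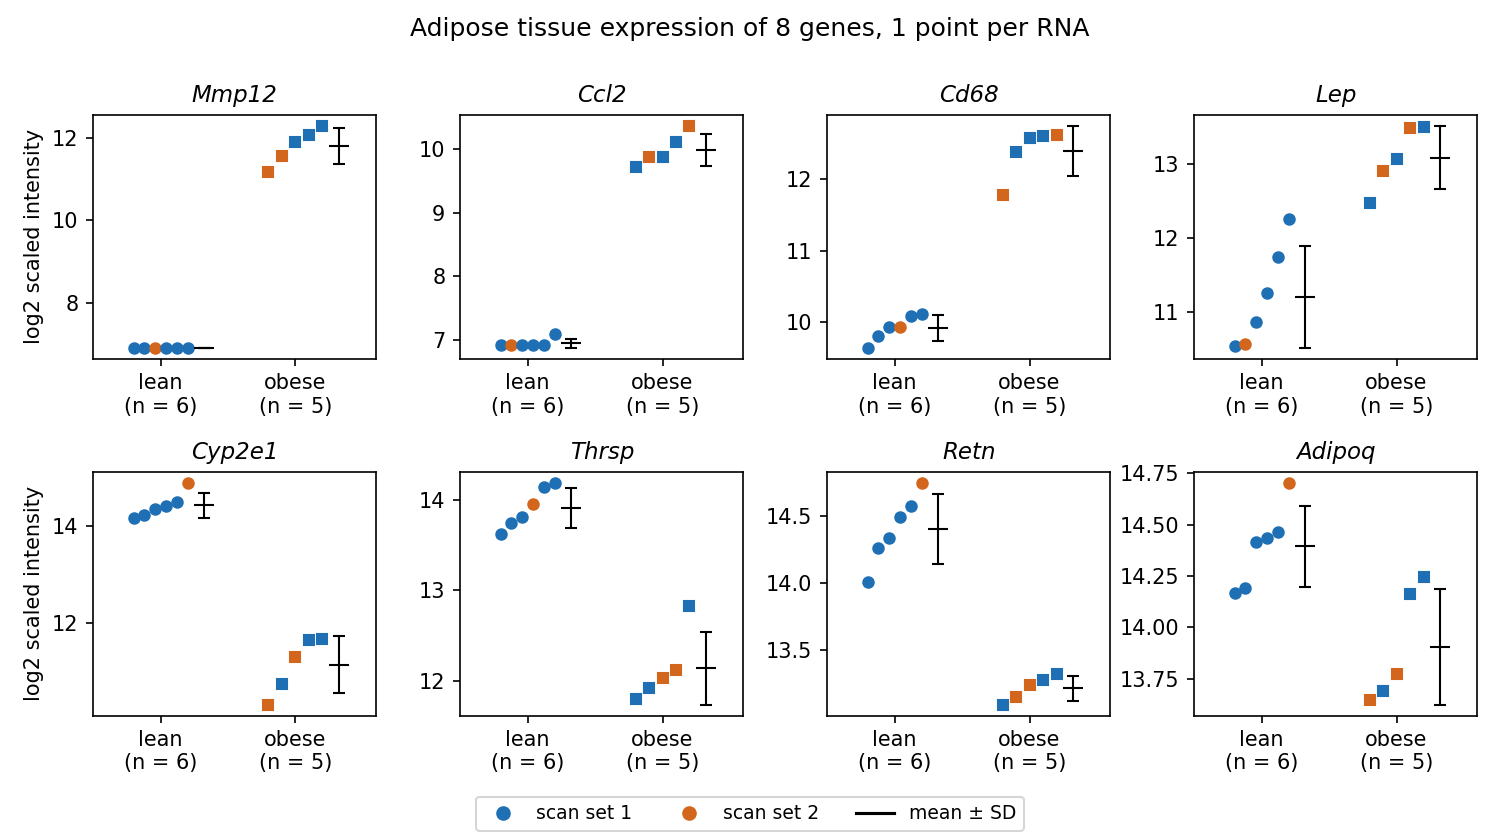
Log2 scaled intensity (vertical axes) of 8 genes in the lean (circles, n = 6) and obese (squares, n = 5) RNAs, 1 point per RNA sorted by value within a group, with mean ± SD beside them and colour for the scan set. The obese values of Mmp12, Ccl2, Cd68 and Lep lie above all lean values and those of Cyp2e1, Thrsp and Retn below, while Adipoq overlaps.

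Among the 16 genes chosen before the data were examined, Cd68, a lysosomal protein of macrophages, rose by 2.47 ± 0.17, from 975 ± 118 (SD, n = 6) to 5502 ± 1165 (SD, n = 5) units. Lep, which encodes leptin, rose by 1.88 ± 0.30, from 2615 ± 1337 to 9023 ± 2531 units (adjusted p = 0.00155). Saa3, an acute phase protein, rose by 2.52 ± 0.51 from a lean mean at background, and by 2.02 on its other probe. Against the 3 lean females alone it gave 2.31 and did not pass (adjusted p = 0.0917). Retn, which encodes the adipocyte hormone resistin, fell by 1.18 ± 0.14. Slc2a4, the insulin-responsive glucose transporter, fell by 1.25 ± 0.23, while its other probe gave -0.83 (adjusted p = 0.274). Fasn, the fatty acid synthase, fell by 0.86 ± 0.15. The other 8 did not pass. Adipoq, which encodes adiponectin, gave -0.49 (adjusted p = 0.0821), but passed after quantile normalization (adjusted p = 0.00522) and with a stricter filter on dim probes (adjusted p = 0.046). Pparg, the adipocyte transcription factor, gave -0.39, Tnf 0.68, Scd1 0.43, Lpl 0.33, Hp -0.18, Ucp1 -0.52 and Fabp4 0.13 (adjusted p = 0.163 to 0.736). Both means of Tnf lay at background. Scd1 passed without the BTBR lean female RNA (0.59, adjusted p = 0.0149), a fit in which obesity and scan set are partly confounded. Cfd and Srebf1 had no probe with a single symbol.

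Of the 23 gene lists, 11 shifted by camera, 6 up and 5 down. With an estimated correlation 7 did, at larger adjusted p. It was 0.000206 for oxidative phosphorylation, 0.000326 for macrophage, 0.0130 for cytoskeleton and 0.0209 for class II and for proliferation genes. For acute phase and for TCA cycle genes it was 0.0247 and 0.0298. The adjusted p of lists below are at the preset correlation unless stated. Macrophage markers rose together: 21 of 31 measured members rose and none fell, and 25 rose when adjusted over the list alone. Their median was 1.31 (adjusted p = 1.07e-35), with 1.32 under the scan block, 1.33 within set 1 and 1.15 within set 2. Besides Mmp12, Ccl2 and Cd68, Lgmn, a lysosomal protease, rose by 2.25. Of 8 class II antigen presentation genes, 2 rose, 5 when adjusted over the list alone, with a median of 0.61 (adjusted p = 0.000609; 0.69, 0.53 and 0.77 by block, set 1 and set 2). Cd74, the invariant chain, rose by 0.76 and H2-Eb1, a class II beta chain, by 0.71, whereas H2-Aa gave 0.72 (adjusted p = 0.0532) and H2-Ab1 0.86 (adjusted p = 0.105). Against the 3 lean males alone Cd74 and H2-Eb1 gave 0.50 and 0.55 and did not pass (adjusted p = 0.221 and 0.268), nor did H2-Eb1 against the lean females (0.88, adjusted p = 0.0545). They also lost their calls with strain (B6, BTBR or cross) as a covariate (adjusted p = 0.0503 and 0.0791), without the filter on dim probes (0.0717 and 0.0788), without a variance trend (0.0799 and 0.0888) and in 7 of the 11 fits that left out 1 RNA. H2-Aa passed with the scan set as a block (0.89, adjusted p = 0.000445). Acute phase and inflammation genes had 5 rises and no fall among 28, 6 rises when adjusted over the list alone, and a median of 0.39 (adjusted p = 1.14e-05; 0.36, 0.39 and 0.43). Ccl7, a monocyte chemokine, rose by 1.77, Mt2, a metallothionein, by 0.80 and Junb, an AP-1 subunit, by 0.62. Junb did not pass against the lean females alone (0.61, adjusted p = 0.0917) and Mt2 within set 1 (0.77, adjusted p = 0.0929).

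The cytoskeleton, proliferation and extracellular matrix lists also shifted up, the last only at the preset correlation. Of 40 cytoskeleton genes, 10 rose and none fell, and 18 rose and 3 fell when adjusted over the list alone. The median was 0.30 (adjusted p = 4.97e-06), with 0.29, 0.44 and 0.16 by block, set 1 and set 2. Lcp1, an actin-bundling protein of leukocytes, rose by 1.86, Anxa1 by 1.46 and Tagln2 by 1.17. Of 23 proliferation genes, 4 rose, 8 when adjusted over the list alone, with a median of 0.18 (adjusted p = 0.00196). The median was 0.22 under the block, 0.15 within set 1 and 0.33 within set 2, where it did not pass with 1 lean RNA (adjusted p = 0.0629). The replication helicase subunit Mcm3 rose by 1.23, Ccnb2, a cyclin of mitosis, by 1.20, Tk1 by 0.65 and Ccnd2 by 0.61. The lean means of Mcm3 and Ccnb2 lay at background. The calls of Mcm3, Tk1 and Ccnd2 were lost in 9, 8 and 9 of the 11 fits that left out 1 RNA. They were also lost against the lean females alone (adjusted p = 0.204, 0.0877 and 0.0951) and the lean males alone (0.0703, 0.195 and 0.155). Ccnb2 gave 1.03 against the males (adjusted p = 0.0654), and within set 1 Tk1 gave 0.74 and Ccnd2 0.48 (adjusted p = 0.0579 and 0.228). Of 43 extracellular matrix genes, 5 rose, and 9 rose and 2 fell when adjusted over the list alone. The median was 0.21 (adjusted p = 0.00488), but adjusted p = 0.195 with an estimated correlation. It was 0.24 under the block, 0.25 within set 1 and 0.03 within set 2, and against the lean females alone it was 0.20 and did not pass (adjusted p = 0.265). Timp1, a protease inhibitor, rose by 2.03, Lox, a collagen cross-linking enzyme, by 1.20, Fbln2 by 1.09 and Bgn by 0.65. Against the lean females alone Lox, Fbln2 and Bgn gave 0.85, 0.85 and 0.58 and did not pass (adjusted p = 0.12, 0.152 and 0.178).

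The lists of oxidative phosphorylation, of the TCA cycle and fatty acid oxidation, of fatty acid and triglyceride synthesis and of redox genes shifted down, the last pair only at the preset correlation. Of 39 oxidative phosphorylation genes, 11 fell and none rose, 23 fell when adjusted over the list alone, and the median was -0.48 (adjusted p = 1.45e-13; -0.50, -0.47 and -0.54 by block, set 1 and set 2). Sdhb, a subunit of succinate dehydrogenase, fell by 0.81, and the complex I subunits Ndufa1, Ndufb5 and Ndufs3 fell by 0.80, 0.69 and 0.60. Against the lean females alone Sdhb, Ndufb5 and Ndufs3 gave -0.84, -0.68 and -0.61 and did not pass (adjusted p = 0.0837, 0.0584 and 0.0997), and Ndufs3 did not against the lean males alone (-0.59, adjusted p = 0.0684). Of 26 genes of the TCA cycle and fatty acid oxidation, 7 fell and none rose, and 13 fell and 1 rose when adjusted over the list alone. Their median was -0.42 (adjusted p = 5.25e-08; -0.37, -0.36 and -0.26). Suclg2 fell by 1.17, Echs1 by 1.08, Etfb by 0.71 and Acadvl by 0.65. Acadvl gave -0.55 within set 1, -0.71 against the lean females alone and -0.58 against the lean males alone, and did not pass (adjusted p = 0.076, 0.0802 and 0.119). Etfb gave -0.54 against the males (adjusted p = 0.0836). Of 16 fatty acid and triglyceride synthesis genes, 6 fell and none rose, and 8 fell and 1 rose when adjusted over the list alone. The median was -0.64 (adjusted p = 1.39e-06; -0.57, -0.44 and -0.88), but adjusted p = 0.0558 with an estimated correlation. Besides Thrsp and Fasn, Acly, which makes cytosolic acetyl-CoA, fell by 1.32 and Tkt by 0.94. Of 27 redox and glutathione genes, 9 fell, and 12 fell and 4 rose when adjusted over the list alone. Their median was -0.10 (adjusted p = 0.00621; adjusted p = 0.17 with an estimated correlation), with -0.24 under the block, -0.15 within set 1 and -0.36 within set 2, where it did not pass with 1 lean RNA (adjusted p = 0.115). Gsta4 fell by 1.22, Aldh2 by 1.18 and Gpx3 by 1.06.

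Skeletal muscle markers had a median of -0.43 (adjusted p = 0.00818; adjusted p = 0.364 with an estimated correlation), with 0 of 18 members changed, also when adjusted over the list alone. The medians were -0.48 under the block, -0.52 within set 1 and -0.30 within set 2. Against the 3 lean males alone the median was -0.06 (adjusted p = 0.668). Myl1 gave -1.47, Des -0.99, Tnnc2 -0.94 and Atp2a1 -0.67. The other 12 lists did not pass (adjusted p = 0.0973 to 0.947). Their medians were -0.52 for thermogenic genes, -0.21 for sex-linked genes, -0.16 for male reproductive tract, 0.15 for lymphocyte and -0.14 for adipocyte identity genes. They were -0.13 for blood cell, -0.10 for mammary and epithelial, 0.08 for endothelial and pericyte, -0.07 for cholesterol synthesis, -0.06 for insulin and glucose handling, -0.05 for chaperone and -0.02 for ribosomal genes. Against the 3 lean females alone, thermogenic genes passed (-1.28, adjusted p = 0.00224), whereas against the 3 lean males alone their median was -0.06. Male reproductive tract markers passed against the lean males alone (-0.36, adjusted p = 0.00975). Sex-linked genes passed against the lean females alone (-0.48, adjusted p = 0.0115), with the scan block (-0.31, adjusted p = 0.0361) and after quantile normalization (-0.27, adjusted p = 0.0441). Without the B6 lean male RNA thermogenic and sex-linked genes passed (adjusted p = 0.0283 and 0.0484), and without the obese B6 RNA sex-linked genes did (adjusted p = 0.0422). Within scan set 2, with its 1 lean RNA, the medians were -0.37 for adipocyte identity and -0.25 for ribosomal genes, against 0.00 and 0.02 within set 1.

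**Figure D2:**
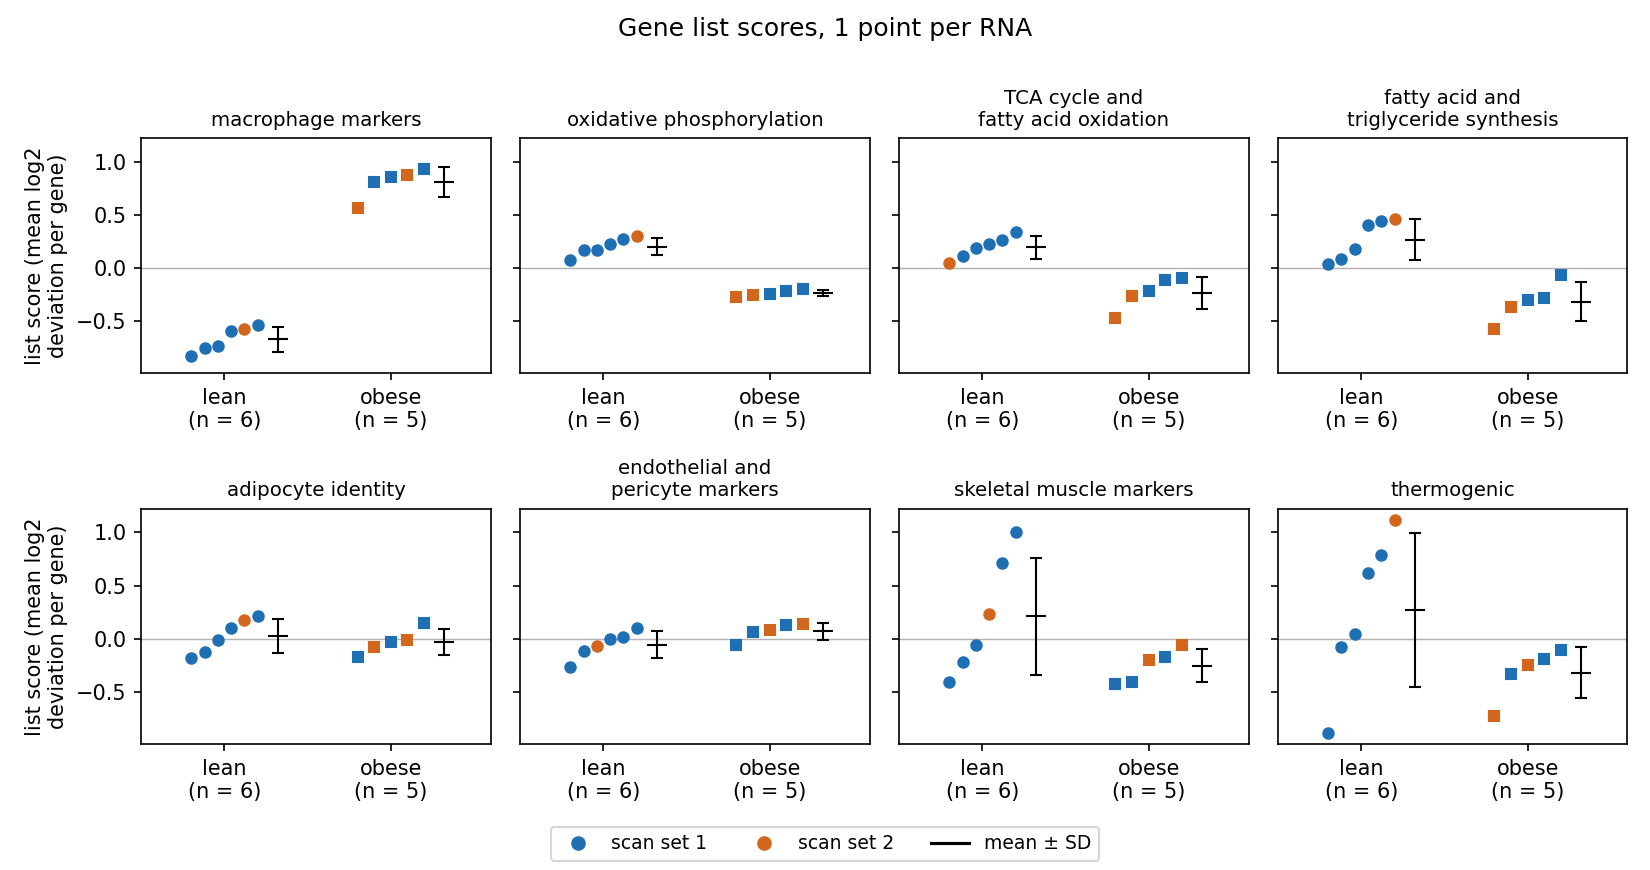
Scores of 8 gene lists (vertical axes, mean over the list's genes of the log2 deviation from each gene's mean over the 11 RNAs) in the lean (circles, n = 6) and obese (squares, n = 5) RNAs, sorted by value within a group, with mean ± SD and colour for the scan set. Macrophage scores averaged -0.67 ± 0.12 in lean and 0.81 ± 0.14 in obese RNAs, and oxidative phosphorylation scores 0.20 ± 0.08 and -0.24 ± 0.03.

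A further comparison asked which genes in the obese RNAs follow plasma glucose, in the order B6, F2 low, F2 medium, F2 high and BTBR. Each position had 1 RNA and the glucose values were not given, so the order was fitted with equal steps. The order began with the B6 and ended with the BTBR strain. Over the whole order, a slope with glucose therefore cannot be told apart from a difference in genetic background. No probe passed by limma (257 at an unadjusted p under 0.05, against 605.4 by chance), also with the scan set as a block (518) and in the F2 RNAs alone (725). Leaving out 1 RNA gave 163 to 1036 such probes, the most without the obese BTBR RNA, and none passed. The named genes with the smallest p all had adjusted p = 1. Htra3, a secreted serine protease, had a slope of 0.65 ± 0.11 (log2 per step ± SE), Lbp, which binds bacterial lipopolysaccharide, -0.38 ± 0.07 and Saa3 -0.85 ± 0.17. The protease inhibitors Serpina1a and Serpina1e had slopes of 0.47 and 0.36, Ahnak 0.32, Ash2l 0.68 and Epx, the eosinophil peroxidase, -0.44. Slopes of the preset genes were 0.27 for Ucp1, 0.20 for Slc2a4, -0.19 for Cd68, 0.16 for Lep, -0.14 for Tnf and 0.13 for Lpl. Those of Hp, Fasn, Pparg, Scd1, Adipoq, Retn and Fabp4 lay between -0.05 and 0.09. Within the 3 F2 RNAs the slopes of Htra3, Lbp and Saa3 were 0.72, -0.32 and -0.42, and none passed. Both scan sets had the same mean position in the order, so the scan block left every slope unchanged by design and tested none of them.

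Of the lists, macrophage markers alone shifted along the order. The median slope was -0.06 (adjusted p = 0.00157), and 25 of 31 members had a negative slope, although no member passed, also when adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.851), in the F2 RNAs alone (-0.11, adjusted p = 0.619) and without the obese BTBR RNA (-0.06, adjusted p = 0.614). C1qb, a complement component, had a slope of -0.28, Hmox1 of -0.31 and Ccl3 of -0.31. The other 22 lists had adjusted p from 0.237 to 0.951. Of the 551 probes changed in obesity, 36.5% had a slope of the same sign as their obesity difference (two-sided exact permutation over 120 orders, p = 0.133).

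**Figure D3:**
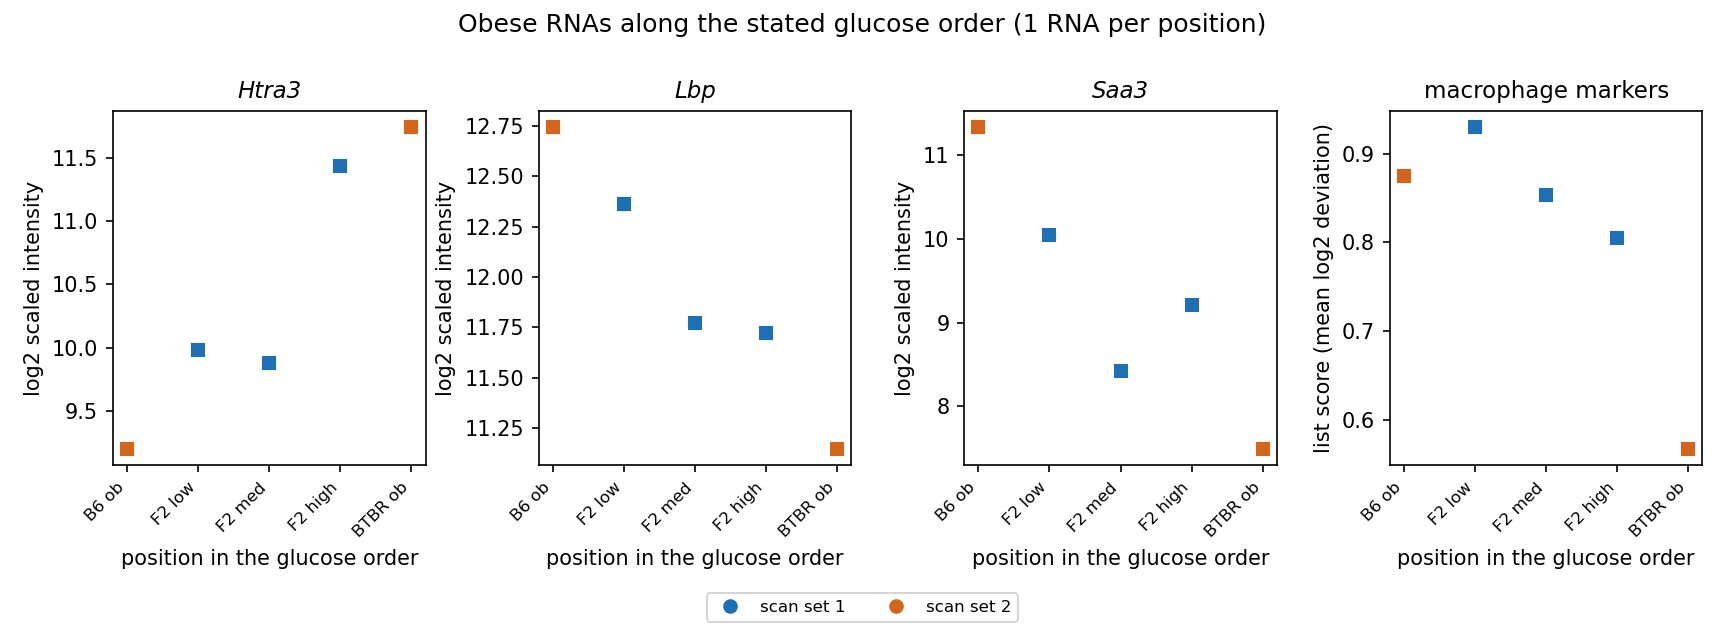
Log2 scaled intensity of Htra3, Lbp and Saa3 and the macrophage list score (vertical axes) in the 5 obese RNAs placed along the glucose order (horizontal axes), 1 RNA per position and colour for the scan set. Macrophage scores were 0.87, 0.93, 0.85, 0.80 and 0.57 from the B6 to the BTBR RNA.

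In lean mice, strain was compared with sex as a covariate. The BTBR lean female was the only lean RNA of scan set 2, so BTBR is partly confounded with scan set. Without the BTBR lean male, BTBR and scan set are wholly confounded, so the count from that fit cannot be read as strain. Between BTBR and B6 no probe passed by limma (752 at an unadjusted p under 0.05). Leaving out 1 RNA gave 386 to 2637 such probes, the most without the BTBR lean male, and 699 without the BTBR lean female, the only lean RNA of scan set 2. Among named genes the smallest p belonged to Ldhb, a lactate dehydrogenase subunit (3.33 ± 0.47), Capn5 (2.53), Cap1 (2.21), Fmo1 (2.16), Serinc3 (1.51), the protease Ctsc (-2.57), the chaperone Cryab (-2.34) and the muscle actin Acta1 (-1.94), with adjusted p = 0.749 to 0.754. The lower mean of Capn5, Cap1 and Ctsc lay at background. Skeletal muscle markers had a median of -0.41 in BTBR (adjusted p = 0.000369; adjusted p = 0.768 with an estimated correlation; -0.40 without the BTBR lean female). None of 18 members passed, and 3 were lower when adjusted over the list alone. Besides Acta1, Myl1 gave -1.95, Tnnc2 -0.91 and Tnni2 -0.85. Without the B6 lean female RNA, 3 probes without a gene symbol were lower in BTBR (log2 -6.57, -4.02 and -6.77, adjusted p = 0.0497). The other 22 lists had adjusted p of at least 0.0586.

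Between F1 and B6 no probe passed by limma (618 at an unadjusted p under 0.05; 184 to 1055 leaving out 1 RNA, the most without the BTBR lean female), and no list did (smallest adjusted p = 0.0517). On values as deposited 5 lists passed, as did 5 with a floor of 5% or of 20% and 2 after quantile normalization. Among named genes the smallest p belonged to Ddit4, an inhibitor of mTOR signalling (2.24 ± 0.28), Pafah1b1 (1.85), Slc25a13 (1.82), Hspg2, which encodes perlecan (1.67), Tbl1x (1.56), Mt1 (1.40), H2-Ab1 (1.38) and the kinase Syk (1.33), all with adjusted p = 0.937.

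Between the 3 female and 3 male lean RNAs, with strain as a covariate, no probe passed by limma (566 at an unadjusted p under 0.05; 227 to 1068 leaving out 1 RNA, with 1064 without the BTBR lean female). Acta1 averaged 7374 ± 3489 (SD, n = 3) units in females and 1526 ± 1104 in males (log2 2.43 ± 0.22, adjusted p = 0.368). Ucp1, the uncoupling protein of brown adipocytes, averaged 1033 ± 430 and 193 ± 41.8 units (2.36 ± 0.31, with the male mean at background). Postn, a matrix protein, gave 2.60, the troponin Tnni2 2.50 and Igfbp6 1.45. Hsd11b1, which regenerates glucocorticoids, gave -1.72, Hpgd -1.53 and Serpina1a -1.27. By list, 17 of 18 skeletal muscle markers were positive, with a median of 0.68 (adjusted p = 1.21e-10, but adjusted p = 0.368 with an estimated correlation; 0.82 without the BTBR lean female). None passed over all probes, and 5 were higher when adjusted over the list alone. Mylpf, at the floor in 2 of the 3 males, gave 2.56, and Tnnc2 gave 0.91. Thermogenic genes had a median of 1.07 (adjusted p = 0.00011, but adjusted p = 0.368 with an estimated correlation; 0.77 without the BTBR lean female), with none passing over all probes and 3 of 5 higher when adjusted over the list alone. Cox8b gave 2.10, Cidea 1.07, with the males at background, and Cox6a2 0.25. Extracellular matrix genes had a median of 0.28 (adjusted p = 0.00011, but adjusted p = 0.368 with an estimated correlation; 0.25), with none passing over all probes and 1 of 43 higher when adjusted over the list alone. Besides Postn, Mfap2 gave 0.90 and Ccn2, at the floor in all 3 females, -1.66. Ribosomal genes had a median of 0.12 (adjusted p = 0.00336, but adjusted p = 0.431 with an estimated correlation; 0.16), where Rps26, with the males at background, gave 0.98 and Rpl12 0.51. Male reproductive tract markers had a median of -0.18 (adjusted p = 0.021, but adjusted p = 0.435 with an estimated correlation; -0.36), where the sperm nuclear proteins Prm1 and Tnp1 gave -3.16 and -3.02 and the sperm lactate dehydrogenase Ldhc -1.75, the females being at background for Tnp1. The Prm1 and Tnp1 differences rested on the B6 and BTBR males, while the F1 male read only 492 and 221 units. No member of the last 2 lists passed, also when adjusted over the list alone. Ribosomal genes lost their call without either F1 lean RNA (adjusted p = 0.079 and 0.0824) and male reproductive tract markers without either B6 lean RNA (adjusted p = 0.121 and 0.133).

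The last comparison asked whether the obesity difference itself differed between BTBR and B6, with 1 obese RNA per strain. Both obese RNAs and the BTBR lean female were of scan set 2, the B6 lean RNAs and the BTBR lean male of set 1. The interaction is therefore partly confounded with scan set. It is wholly confounded without the BTBR lean male, the fit with the highest count below. No probe passed by limma (291 at an unadjusted p under 0.05; 161 to 1351 leaving out 1 lean RNA), and no list did (smallest adjusted p = 0.191). Among named genes the smallest p belonged to Lpgat1 (5.77), Krt19 (3.44), Mis18a (2.72), S100a4 (2.26), Cmtm4 (-4.35), Zbtb7b (-3.35), Lhb (-2.75) and Parg (-2.71), all with adjusted p = 0.999. In data simulated for this design, 0 of 66 probes changed 8-fold were recovered, so differences of that size were not detectable here.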

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

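The tests of the adipocyte share, of the muscle markers and of Ucp1 below were chosen only after the result was seen. Of 106 sets of values examined (30 genes and 23 list scores in each of the 2 groups), 7 held an RNA far from the others of its group, against 5.3 by chance. In the lean group, the B6 male had the highest Ccl2 (log2 7.09; the other 5 were at the floor, 6.92) and the highest Slc2a4 (11.9; nearest 11.3), and the BTBR female had the highest Tnf (8.07; nearest 7.16). In the obese group, the B6 RNA had the lowest Net1 (7.58; nearest 9.11), the lowest Zfp467 (8.24; nearest 9.20) and the lowest extracellular matrix score (-0.0101; nearest 0.152). The obese BTBR RNA had the lowest Cd68 (11.8; nearest 12.4).

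Macrophage markers were higher in obese RNAs. A difference between scan sets would forbid the median of 1.33 found within set 1, and the sex make-up of the lean group the 1.29 found against lean males, the lower of the values for each sex. A lower share of adipocyte RNA would raise markers of other cell types alike, but the macrophage median exceeded that of 14 endothelial and pericyte genes by 1.23 (permutation of genes between lists, which are not independent replicates, p = 0.00528). More macrophage RNA in obese adipose tissue may account for the pattern, as a hypothesis found and tested on the same data. More macrophages and higher expression per macrophage are not separated by these values.

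Oxidative phosphorylation genes were lower in obese RNAs. Bright signals on the B arrays of the obese B6 and BTBR RNAs were compressed, but scan set 1, which holds neither array, gave a median of -0.469. Muscle or brown fat RNA in the lean females could also raise the lean values, but against the lean males alone the median was -0.419. The lower transcript levels of these genes therefore remain without either source, and what lowers them was not tested. A changed mix of cell types stays open and was not tested for this list.

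Skeletal muscle and thermogenic markers had higher medians in lean females by camera, but no member passed over all probes, and both calls were lost with an estimated correlation (adjusted p = 0.368 for each). The muscle median exceeded those of 100% of 10000 random lists matched on mean signal, which restates the shift and decides nothing on muscle RNA in the female samples. Ucp1, which muscle does not make, was at 643 to 1494 units in the females, above the background probes. In the males it lay at background (log2 difference 2.36). Muscle alone would not raise Ucp1, but the difference did not pass over all probes (adjusted p = 0.462 by limma). Ucp1 also belongs to the thermogenic list that set the pattern, so its level cannot exclude muscle alone. Muscle RNA along with brown fat in the dissected tissue, or a sex difference in the tissue itself, stays open as well and untested. Of the 5 measured thermogenic genes, 3 (Cidea, Cox8b and Cox6a2) are also in another list.

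Other splits of the RNAs were fitted for 3 counts. For obese against lean, 2 of 100 splits into 6 and 5 gave at least the 551 probes found, the real split included, so a chance split can be excluded at that level. The highest other split gave 850; it is the real split with the BTBR lean female moved to the obese side, which put all of scan set 2 on one side. The other splits with all of scan set 2 on one side gave 0 to 5 probes. For female against male, all 10 splits gave 0 probes by limma (real 0, highest other 0; 566 at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. Along the glucose order, 49 of 60 orders gave at least 257 probes at an unadjusted p under 0.05 (highest other 2292), so a chance order cannot be excluded. For the macrophage slope, 6 of 60 orders lay as far from the mean of all genes (0.0785, highest other 0.0867), so chance cannot be excluded there either.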

How the results depend on the processing

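The fits within scan set 2 and on the A array alone were chosen only after the result was seen. So were the obesity list fits within scan set 1 and against each lean sex alone. The glucose list fits in the F2 RNAs alone and with the scan block were chosen then too. Of 1458 alternative values for the 53 named obesity calls, 1195 stayed past the threshold, 263 did not and 0 changed direction; all 53 lost their call under exact permutation, Wilcoxon and within scan set 2, 14 against lean females and 12 against lean males. Of 242 values for the 11 lists, 233 stayed and 8 did not, and the extracellular matrix list, set against the other genes by camera, pointed down within scan set 2, which has 1 lean RNA (median 0.0336, adjusted p = 0.782); the cause was not tested. The permutation and Wilcoxon tests passed no gene, even with fully separated groups. The number of RNAs sets their smallest p, and too few probes reached it to pass after adjustment. Calls lost under them therefore do not tell one gene from another. Under these tests and the 2-fold minimum the reported differences were kept, so the direction could not change there. Results that did not pass in the reported fits changed sign 9 times for obesity genes, 21 times for lists and 17 times for glucose slopes, and 17 gene and 10 list values of theirs passed under an alternative.

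The 551 probes became 357 against lean females, 337 against lean males, 300 with a 2-fold minimum and 278 of the 6077 probes of the A array, where fewer RNAs or probes entered, or a further threshold was set. They became 0 by exact permutation (1998 at an unadjusted p under 0.05), 0 by Wilcoxon (1602) and 0 by limma within scan set 2 (1448), where 3 RNAs remained. By permutation and by Wilcoxon, fully separated probes did not pass either. The number of RNAs sets their smallest p, and too few probes reached it to pass after adjustment. Leaving out 1 RNA gave 380 to 952, the highest without the BTBR lean female. Without it every lean RNA is of scan set 1, while the obese B6 and BTBR RNAs are of set 2. Obesity and scan set are therefore partly confounded in that fit, and the cause of the higher count was not tested. For single genes, leaving out 1 RNA ended the calls of Cd74, H2-Eb1, Mcm3, Tk1 and Ccnd2 in 7, 7, 9, 8 and 9 of 11 fits, and of Bgn without the F2 high or F2 low RNA (adjusted p up to 0.0527). The other 47 named calls held in all 11.

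With an estimated correlation, 7 lists passed for obesity and 0 for glucose, BTBR and sex, where camera at the preset value gave 11, 1, 1 and 5. In the F2 RNAs alone, 0 lists passed for glucose. For BTBR, 4 passed on values as deposited. For F1, where 0 passed, 5 did as deposited, 2 after quantile normalization, and 5 with a floor of 5% or of 20%. Leaving out 1 RNA gave 11 to 13 lists for obesity, 0 to 2 for glucose, 1 to 4 for BTBR, 0 to 3 for F1, 4 to 6 for sex and 0 to 3 for the interaction; probes stayed at 0 by limma except for BTBR, 0 to 3 (3 without the B6 lean female). The causes were not tested. The same-sign share was 35.0% to 37.0%.

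By replicate number, no paired analysis was possible because the labels give none. Strain pairs the lean female and male RNAs and was a term in the sex fit, and with strain (B6, BTBR or cross) as a covariate 380 probes rose and 286 fell in obese RNAs. The interaction could not be fitted without an obese RNA. Signal over background limits genes near the floor, such as Mmp12, Ccl2 and Tnf in lean RNAs.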

Other observations

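The values of Mest, the sperm cell transcripts, the distances and the bright probes were picked after the data were seen, whereas the other genes in this part follow the rule for list members. Mest, an imprinted gene linked to adipocyte size, was at 3209 to 11192 scaled units in the 5 obese RNAs and at 1038 to 1455 in the lean females and 2314 to 4796 in the lean males (log2 difference from all 6 lean RNAs 2.03, adjusted p = 0.00675 by limma). Among the obese RNAs, the lowest value, 3209, was that of BTBR and lay within the range of the lean males. Sox17, an endothelial transcription factor, rose by 1.11, Cd72, a B cell antigen, by 1.80 and S100a8, a neutrophil protein, by 1.06, although their lists did not shift. The lean means of Sox17 and Cd72 lay at background. Gys1, the glycogen synthase, fell by 0.86, Svs2 by 1.13 and Hspd1, a mitochondrial chaperone, by 0.56, while Atf3, a stress-induced transcription factor, rose by 0.84.

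Transcripts of sperm cells stood out in 2 lean males. Prm1 was at 21583 units in the B6 male and 12161 in the BTBR male, and at 275 to 1574 in the other 9 RNAs. Tnp1 was at 5865 and 3600 units in these males and at 130 to 326 in the others. Prm2 was at 12806 and 4247, against 1491 to 2883. The F1 lean male did not share these levels.

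The Xist probe, too dim to enter the tests, had deposited intensities of 718, 260 and 553 in the lean females and 46, 117 and 62 in the lean males. In the obese RNAs, whose sex was not labelled, it read 31 to 96. On this 1 dim probe every obese value lay below all lean females and no higher than the highest lean male. If the obese RNAs were male, the fits against the lean males alone would be the ones matched for sex. The Y-linked Kdm5d averaged 371 scaled units in the lean and 197 in the obese RNAs, the latter at background (log2 -0.98, adjusted p = 0.0323 by limma). This probe read 330 to 376 units in the lean females and 330 to 418 in the lean males. It did not tell the lean sexes apart, so its lower level in the obese RNAs says nothing on their sex.

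In the distance over all probes, the BTBR lean female lay nearest to the obese B6 RNA (71.8) and then to the obese BTBR RNA (72.5), both of its own scan set. On the B arrays, 518 probes with a mean above 4000 units had a median obese minus lean difference of -0.14 (-0.09 within scan set 1), against 0.04 for 437 such probes on A.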
